A study of Mus musculus with 12 samples.

How the data were processed

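Livers of wild-type C57BL/6 female mice, intact or ovariectomized, were collected 6 h after PBS or dexamethasone at 1 mg/kg. RNA was extracted with TRIzol, purified on RNeasy columns, made into libraries with an Illumina TruSeq kit, pooled and sequenced on an Illumina NextSeq instrument, per the labels' protocols. Trim Galore, TopHat2, HTSeq, DESeq and DESeq2 were used and the mouse genome build was mm9, per the submitters' processing notes, which give no versions in the form used here. The authors deposited 1 table of log2 values, made from gene counts and normalized between libraries, per the labels' description. The exact transformation and the gene annotation are not given in the sources used here.

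The table held 24962 entries with values from -2.22 to 22.03, and 6294 entries were listed at 0 in every library. The values may have been shrunk at low levels, which was not tested, and the fold changes of low genes would then be understated. Read counts and depth cannot be recovered from such values, so no counting interval or detection limit is given. For 392 symbols with several entries, the entry with the highest mean was kept, which left 24033 symbols. Genes with a mean of at least 4 over all libraries were tested, 12965 in number.

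The 4 groups were fitted together in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with a trend of the prior variance on the mean; 8 residual degrees of freedom). The 5 comparisons were dexamethasone against vehicle in each gonadal state, ovariectomized against intact under each treatment, and the difference between the responses. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Of 34 gene lists, 30 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists; camera with an estimated correlation and fry were alternatives. Counts of list members are over those measured. Fry tests whether the members of a list move one way and does not compare them with other genes. The score of the dexamethasone response was tested with a two-sided exact permutation of gonadal state within each treatment.

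The gene lists, the tests of genes and lists, the comparisons, the alternatives given first below and the rule for the genes named were fixed before the data were examined. The tests of technical explanations were set after a first fit had shown the patterns they address. The rule named, in each comparison, up to 10 genes with the largest rise and up to 10 with the largest fall among genes that passed and whose libraries did not overlap between the groups (a share of 10% by chance; no such condition for the difference between responses). It also named up to 4 members of each list that passed, by size, and Nr3c1, Esr1, Fkbp5, Per1 and Tsc22d3 whatever their value. Some genes that the rule takes are not reported here, though counts over named genes include them. Clone and locus symbols were passed over: 1 among the falls in intact females, 1 among the rises and 1 among the falls in ovariectomized females, and 1 among the lower responses.

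The alternatives were no filter, a mean of at least 6, a pseudocount of 8 on the linear scale, recentring to the same median, quantile normalization, no variance trend, a robust prior, library weights, a minimum absolute log2 fold change of 1, only the libraries compared, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were the removal of each library's trend on transcript length and GC content (natural splines, 4 degrees of freedom), leaving out genes with copies, and recentring for the list tests. Transcript length, GC content and shared sequence came from the GRCm38 transcripts, matched by symbol for 12898 genes (99.5%). A gene counted as having copies when at least 20% of its 50-base words occurred in another gene. No coordinates are given, because that build is not the one of the deposited table.

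The fit was tested on simulated data in which 50 genes per size of change were altered among 12965. Shares recovered follow the order of comparisons above, intact before ovariectomized and vehicle before dexamethasone. They were 100%, 96%, 96%, 94% and 90% for a log2 change of 1. For 0.3 they were 38%, 34%, 36%, 24% and 18%, with 5 to 9 false calls. Shares of 50 genes do not rank the comparisons. The real data hold trends and more changed genes, so false calls may differ.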

Results

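Liver RNA from wild-type C57BL/6 female mice was sequenced in 12 libraries that fall into 4 groups of 3: intact or ovariectomized females, each given vehicle or dexamethasone. Dexamethasone (1 mg/kg, 6 h) is a synthetic glucocorticoid, and ovariectomy removes the main source of oestrogen. The design asks which genes respond in each gonadal state, which differ between gonadal states under each treatment, and for which the response itself differs. Levels are log2 expression values as deposited, which no longer hold the read depth of each library. Differences are log2 fold changes ± SE from limma, with n = 3 libraries per group and 12965 genes tested. The labels do not say that replicates are separate animals, so the p-values measure the spread between these samples. Library medians over the genes tested lay between 8.82 and 8.86. Replicate libraries differed by a root mean square of 0.172 to 0.32 per gene. Vehicle and dexamethasone libraries lay on opposite sides of the first principal component, which held 49.9% of the variance. Gene lists are described by how many members passed, since other splits of the same libraries passed as many lists or more in each comparison.

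Among the largest changes with dexamethasone in intact females were the rises of Fam107a, Tff3 and Sult1e1 and the fall of Acot3. Fam107a (Entrez 268709), an actin-binding protein known to respond to glucocorticoids, rose by 3.72 ± 0.34, adjusted p = 1.23e-05. Its level went from 6.38 ± 0.022 (mean ± SD) to 10.11 ± 0.84, or 13.2-fold. Tff3 (Entrez 21786), a trefoil peptide of mucosal surfaces, rose by 3.74 ± 0.57 and varied among the dexamethasone libraries (SD 1.6). Sult1e1 (Entrez 20860), the sulfotransferase that inactivates oestrogens, rose by 3.28 ± 0.22, and Lcn2, a siderophore-binding acute phase protein, by 2.68 ± 0.2. Acot3 (Entrez 171281), a peroxisomal acyl-CoA thioesterase, fell by 2.88 ± 0.3.

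Other large rises in intact females were those of Eif4ebp3, a repressor of translation initiation (2.83 ± 0.1), Serpina4-ps1 (2.55 ± 0.49), the cell cycle inhibitor Cdkn1a (2.4 ± 0.36) and Treh, which encodes trehalase (2.4 ± 0.19). Gadd45g rose by 2.14 ± 0.5. Hsd3b1, a steroid dehydrogenase gene, rose by 2.34 ± 0.7, adjusted p = 0.0571 to 0.0591 without intact dexamethasone replicate 1 or 3. Large falls were those of Gbp10, a guanylate-binding GTPase (-2.42 ± 0.14), the desmosomal cadherin Dsg1c (-2.18 ± 0.22), Abcb1a, which encodes the drug efflux pump P-glycoprotein (-2.02 ± 0.094), Rnf186 (-1.91 ± 0.12) and the GABA-B receptor subunit Gabbr2 (-1.87 ± 0.11). Abhd2 (-1.84 ± 0.16), the thioesterase Acot4 (-1.78 ± 0.13), Rnf125 (-1.75 ± 0.2) and Abcd2, a peroxisomal transporter of very long chain fatty acids (-1.74 ± 0.067), also fell. Eif4ebp3, Gbp10, Dsg1c, Abcb1a and Acot3 are uncertain, because 65.5%, 84.1%, 29.6%, 22.5% and 21.2% of their 50-base words also occur in another gene. Nr3c1, the glucocorticoid receptor gene, fell by 0.57 ± 0.054. Fkbp5, a chaperone gene induced by glucocorticoids, rose by 1.28 ± 0.22, the clock gene Per1 by 0.64 ± 0.16 and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, by 0.59 ± 0.15. Esr1, which encodes oestrogen receptor alpha, did not pass (-0.88 ± 0.35, adjusted p = 0.0558). Its level in dexamethasone replicate 2 was 8.01, against 8.91 and 8.93 in the other replicates.

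Of known glucocorticoid receptor targets, 14 of 23 rose and 2 fell (14 and 2 adjusted over the list alone). This list had a camera adjusted p of 0.0112 (adjusted p = 0.683 with an estimated correlation). The phosphatase gene Dusp1 rose by 1.88 ± 0.21, Ddit4, an inhibitor of mTORC1, by 1.62 ± 0.38 and Lpin1, a phosphatidate phosphatase, by 1.59 ± 0.29. Of amino acid catabolism genes, 13 of 36 rose and 8 fell (13 and 8 adjusted over the list alone), with a camera adjusted p of 0.116. Tdo2, the tryptophan dioxygenase gene, rose by 1.13 ± 0.11 and the serine dehydratase gene Sds by 1.38 ± 0.24. Of gluconeogenesis genes, 8 of 20 rose and 2 fell (8 and 2 adjusted over the list alone), with a camera adjusted p of 0.101, and the glucose-6-phosphatase gene G6pc rose by 0.68 ± 0.2.

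Of cholesterol synthesis and SREBP2 targets, 0 of 24 rose and 11 fell (0 and 11 adjusted over the list alone) in intact females. They had a camera adjusted p of 0.0156 (adjusted p = 0.707 with an estimated correlation, 0.0686 with fry), and adjusted p = 0.0597 to 0.0636 without replicate 1 of intact vehicle or 2 of intact dexamethasone. The sterol carrier gene Stard4 fell by 1.56 ± 0.17. Of fatty acid oxidation and PPARalpha targets, 1 of 30 rose and 15 fell (1 and 15 adjusted over the list alone). These targets had a camera adjusted p of 0.0164 (adjusted p = 0.707 with an estimated correlation), and adjusted p = 0.101 under quantile normalization (0.00367 to 0.707 over all alternatives), and Ppara itself fell by 1.2 ± 0.11. Of bile acid synthesis and transport genes, 2 of 19 rose and 12 fell (2 and 12 adjusted over the list alone). This group had a camera adjusted p of 0.0261 (adjusted p = 0.683 with an estimated correlation), adjusted p = 0.058 without intact dexamethasone replicate 3, and adjusted p = 0.0836 under quantile normalization (0.00119 to 0.683 over all alternatives). The sterol transporter gene Abcg8 changed by -1.39 ± 0.1, the bile-acid-induced repressor Nr0b2 by -1.37 ± 0.22 and Cyp8b1, an enzyme of cholic acid synthesis, by 1.16 ± 0.16. Of pericentral hepatocyte genes, 1 of 16 rose and 9 fell (1 and 9 adjusted over the list alone). Pericentral genes had a camera adjusted p of 0.0261 (adjusted p = 0.683 with an estimated correlation), adjusted p = 0.0756 without intact dexamethasone replicate 3, and adjusted p = 0.0657 under quantile normalization (0.00507 to 0.683 over all alternatives), and Lgr5 changed by -1.14 ± 0.3.

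Of interferon response genes, 1 of 32 rose and 28 fell (1 and 28 adjusted over the list alone) in intact females. Interferon response genes had a camera adjusted p of 1.05e-08 (adjusted p = 0.381 with an estimated correlation). The guanylate-binding proteins Gbp6 and Gbp7 changed by -1.4 ± 0.11 and -1.3 ± 0.11 and the GTPase gene Igtp by -1.14 ± 0.18. Of antigen presentation genes, 0 of 16 rose and 8 fell (0 and 8 adjusted over the list alone). Antigen presentation genes had a camera adjusted p of 0.0261 (adjusted p = 0.707 with an estimated correlation), adjusted p = 0.104 without intact vehicle replicate 2, and adjusted p = 0.069 under quantile normalization (0.00388 to 0.707 over all alternatives), and the class II transactivator gene Ciita changed by -0.67 ± 0.15. Of B cell markers, 0 of 7 rose and 6 fell (0 and 6 adjusted over the list alone). B cell markers had a camera adjusted p of 0.0286 (adjusted p = 0.683 with an estimated correlation), and adjusted p = 0.058 to 0.0629 without replicate 2 of intact vehicle or 3 of intact dexamethasone, and Ms4a1, which encodes CD20, changed by -0.71 ± 0.11. The lists of cytokines (1 of 23 rose and 6 fell, camera adjusted p = 0.128), T and NK cells (0 of 12 rose and 0 fell, camera adjusted p = 0.318), macrophages (0 of 17 rose and 7 fell, camera adjusted p = 0.0665) and acute phase proteins (9 of 27 rose and 5 fell, camera adjusted p = 0.215) did not pass. Of stellate cell and fibroblast markers, 10 of 16 rose and 0 fell (11 and 0 adjusted over the list alone). Stellate markers had a camera adjusted p of 0.00176 (adjusted p = 0.683 with an estimated correlation), with Pdgfra at 0.95 ± 0.12 and Ecm1 at 0.75 ± 0.1. Of sinusoidal endothelial markers, 6 of 16 rose and 1 fell (6 and 1 adjusted over the list alone). Endothelial markers had a camera adjusted p of 0.0288 (adjusted p = 0.707 with an estimated correlation, 0.0728 with fry), and adjusted p = 0.0794 to 0.104 without replicate 2 of intact vehicle or 3 of intact dexamethasone, with the hyaluronan receptor gene Lyve1 at 1.56 ± 0.27 and the scavenger receptor gene Stab1 at 0.84 ± 0.12. Of immediate early and heat shock genes, 8 of 20 rose and 0 fell (5 and 0 adjusted over the list alone). This stress list had a camera adjusted p of 0.0261 (adjusted p = 0.683 with an estimated correlation), adjusted p = 0.0776 without intact dexamethasone replicate 3, and adjusted p = 0.0849 with the length and GC trend removed (0.00524 to 0.683 over all alternatives), with Hspa1a at 1.02 ± 0.25 and Jun at 0.78 ± 0.17.

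In all, 2959 genes rose and 3364 fell with dexamethasone in intact females (limma, Benjamini-Hochberg adjusted p under 0.05), 48.8% of those tested, of which 135 and 178 changed at least 2-fold; rises and falls numbered 3048 and 3306 recentred to the same median, 3163 and 3075 under quantile normalization. Of 30 gene lists 11 passed, 6 did without intact dexamethasone replicate 3, and 0 did with an estimated correlation. The fold change followed transcript length across genes, which are not independent replicates (Spearman's rho -0.26).

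**Figure D1:**
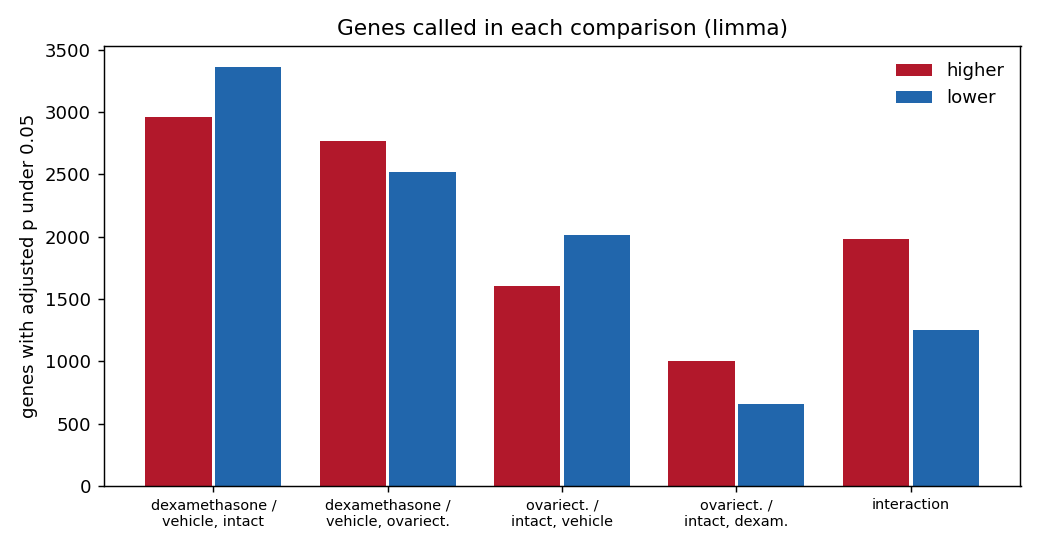
Bars give the number of genes (y axis) higher or lower at a limma adjusted p under 0.05 in each of the 5 comparisons (x axis), each over n = 3 libraries per group. The tallest bars are those of dexamethasone in intact females, with 2959 genes higher and 3364 lower, and the shortest those of ovariectomized against intact females given dexamethasone, with 1004 and 658.

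In ovariectomized females, several of the genes with the largest rises in intact females rose too, and a number of immediate early genes fell. Fam107a rose by 4.17 ± 0.34, adjusted p = 8.4e-06, Lcn2 by 4.06 ± 0.2, Cdkn1a by 3.81 ± 0.36 and Sult1e1 by 3.49 ± 0.22. Nr4a1 (Entrez 15370), an orphan nuclear receptor of the immediate early class, fell by 4.65 ± 0.28 (adjusted p = 1.16e-06), from 11.14 ± 0.79 (mean ± SD) to 6.49 ± 0.091. Its relative Nr4a2 fell by 2.4 ± 0.22. Ppp1r3g (Entrez 76487), a subunit that targets protein phosphatase 1 to glycogen, fell by 3.61 ± 0.3.

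Other large rises were those of Treh (2.93 ± 0.19), Eif4ebp3 (2.89 ± 0.1), the transcription factor Zbtb16, also called PLZF (2.89 ± 0.3), Serpina4-ps1 (2.86 ± 0.49), the serum amyloid gene Saa1 (2.79 ± 0.24) and the plasma protease inhibitor gene Serpina3k (2.66 ± 0.33). Saa1 is uncertain, because 31.5% of its 50-base words occur in other genes. Other large falls were those of the ephrin gene Efna3 (-2.49 ± 0.17), the ERK phosphatase gene Dusp6 (-2.33 ± 0.15), Zfp395 (-2.14 ± 0.2), Rnf186 (-2.08 ± 0.12), the clock output gene Dbp (-2.03 ± 0.3) and Acot3 (-2.03 ± 0.3). Fkbp5 rose by 2.29 ± 0.22 and Tsc22d3 by 1.13 ± 0.15. Per1 (0.36 ± 0.16, adjusted p = 0.091), Esr1 (0.78 ± 0.35, adjusted p = 0.0928) and Nr3c1 (-0.03 ± 0.054, adjusted p = 0.636) did not pass. The Nr3c1 value was 0.01 without ovariectomized dexamethasone replicate 2, the library in which Esr1 was at 7.88, against 9.33 and 9.47 in the other replicates.

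Glucocorticoid receptor targets again stood out: 14 of 23 rose and 2 fell (16 and 2 adjusted over the list alone). These receptor targets had a camera adjusted p of 4.38e-05 (adjusted p = 0.546 with an estimated correlation), with Ddit4 at 2.39 ± 0.38 and Lpin1 at 2.33 ± 0.29. Of amino acid catabolism genes, 16 of 36 rose and 2 fell (16 and 2 adjusted over the list alone). Amino acid catabolism had a camera adjusted p of 0.000259 (adjusted p = 0.612 with an estimated correlation). Tdo2 rose by 1.74 ± 0.11, the lysine-degrading enzyme gene Aass by 1.68 ± 0.11 and the urea cycle gene Cps1 by 1.38 ± 0.12. Of gluconeogenesis genes, 12 of 20 rose and 2 fell (12 and 3 adjusted over the list alone). Gluconeogenesis had a camera adjusted p of 0.0191 (adjusted p = 0.482 with an estimated correlation), and adjusted p = 0.05 under quantile normalization (0.000649 to 0.482 over all alternatives), and the alanine aminotransferase gene Gpt2 rose by 1.08 ± 0.089. Of insulin and glucose handling genes, 4 of 20 rose and 8 fell (4 and 8 adjusted over the list alone), with a camera adjusted p of 0.183. The insulin receptor substrate gene Irs1 fell by 1.4 ± 0.12. Of acute phase proteins, 15 of 27 rose and 1 fell (16 and 1 adjusted over the list alone). Acute phase proteins had a camera adjusted p of 4.01e-05 (adjusted p = 0.482 with an estimated correlation), and the orosomucoid gene Orm3 rose by 2.48 ± 0.26. Of endoplasmic reticulum stress genes, 10 of 21 rose and 2 fell (10 and 3 adjusted over the list alone). This stress list had a camera adjusted p of 0.0322 (adjusted p = 0.756 with an estimated correlation), adjusted p = 0.102 without ovariectomized dexamethasone replicate 1, and adjusted p = 0.108 under quantile normalization (0.00401 to 0.756 over all alternatives), and Creld2 and Manf rose by 0.97 ± 0.12 and 0.95 ± 0.15.

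Of interferon response genes, 1 of 32 rose and 28 fell (1 and 29 adjusted over the list alone) in ovariectomized females. Interferon response genes had a camera adjusted p of 3.06e-11 (adjusted p = 0.201 with an estimated correlation), with Ifit1 at -1.15 ± 0.093, Ifit3 at -1.06 ± 0.1 and Gbp6 at -1.05 ± 0.11. Of NF-kappaB cytokines and chemokines, 2 of 23 rose and 12 fell (2 and 13 adjusted over the list alone). The cytokine list had a camera adjusted p of 0.0052 (adjusted p = 0.482 with an estimated correlation), with the interleukin genes Il1b at -1.61 ± 0.19 and Il1a at -1.1 ± 0.1. Of antigen presentation genes, 0 of 16 rose and 10 fell (0 and 11 adjusted over the list alone). Antigen presentation genes had a camera adjusted p of 0.00259 (adjusted p = 0.721 with an estimated correlation), with H2-Ab1 at -0.76 ± 0.16. Of B cell markers, 0 of 7 rose and 6 fell (0 and 6 adjusted over the list alone). B cell markers had a camera adjusted p of 0.00106 (adjusted p = 0.482 with an estimated correlation). Of Kupffer cell and macrophage markers, 1 of 17 rose and 9 fell (1 and 10 adjusted over the list alone). Macrophage markers had a camera adjusted p of 0.0145 (adjusted p = 0.756 with an estimated correlation, 0.0842 with fry), and adjusted p = 0.0733 to 0.0978 without replicate 1 of ovariectomized vehicle or 3 of ovariectomized dexamethasone. The list of T and NK cells did not pass (0 of 12 rose and 1 fell, camera adjusted p = 0.549). Among macrophage markers the haemoglobin scavenger receptor gene Cd163 rose by 1.02 ± 0.19 and Cd68 fell by 0.55 ± 0.081. Of cholangiocyte markers, 0 of 8 rose and 5 fell (0 and 5 adjusted over the list alone). Cholangiocyte markers had a camera adjusted p of 0.0191 (adjusted p = 0.482 with an estimated correlation), and adjusted p = 0.0666 under quantile normalization (0.00283 to 0.482 over all alternatives), with the keratin gene Krt23 at -1.5 ± 0.26 and Spp1, which encodes osteopontin, at -0.58 ± 0.088. Of immediate early and heat shock genes, 1 of 20 rose and 9 fell (1 and 9 adjusted over the list alone), with a camera adjusted p of 0.0539. Egr1 changed by -1.45 ± 0.29, Atf3 by -1.41 ± 0.31 and Junb by -1.12 ± 0.18. Of neutrophil markers, too few for a test as a list, S100a9 (-1.17 ± 0.22), S100a8 (-0.85 ± 0.24, adjusted p = 0.0509 to 0.063 without replicate 3 of ovariectomized vehicle or 1 of ovariectomized dexamethasone) and Csf3r (-0.66 ± 0.09) fell and Lcn2 rose (4.06 ± 0.2).

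Altogether 2765 genes rose and 2518 fell in ovariectomized females (limma adjusted p under 0.05), 40.7% of those tested, and 200 and 159 changed at least 2-fold; rises and falls numbered 2479 and 2808 recentred to the same median, 2625 and 2558 under quantile normalization. Of the lists 11 passed, and 0 did with an estimated correlation.

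Circadian clock genes moved in both directions in both dexamethasone comparisons. In intact females 5 of 18 rose and 8 fell (5 and 9 adjusted over the list alone), with a camera adjusted p of 0.718. Arntl, which encodes the clock activator BMAL1, rose by 1.9 ± 0.18 and Dbp changed by -1.43 ± 0.3. In ovariectomized females 4 of 18 rose and 6 fell (4 and 6 adjusted over the list alone), with a camera adjusted p of 0.823. Arntl rose by 2.43 ± 0.18, Cry1 by 1.32 ± 0.12, and Nr1d1 changed by -1.35 ± 0.22.

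The responses of the 2 gonadal states were compared gene by gene. Pearson's r between the log2 fold changes in intact and ovariectomized females was 0.58 and Spearman's rho 0.47, across genes, which are not independent replicates. The comparisons share no library. Both responses called 1285 genes higher, where independent lists of the same sizes would share 631.1, and 1369 lower, where they would share 653.3. In opposite directions, 369 genes were called. A score per library was the mean of 3476 genes that rose in the average of both responses minus that of 3628 genes that fell. It moved by 0.8 in intact and 0.71 in ovariectomized females. The difference of -0.08 did not pass a two-sided exact permutation test (p = 0.35, 400 assignments, smallest possible p 0.005), which does not show that the responses were equal in size.

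**Figure D2:**
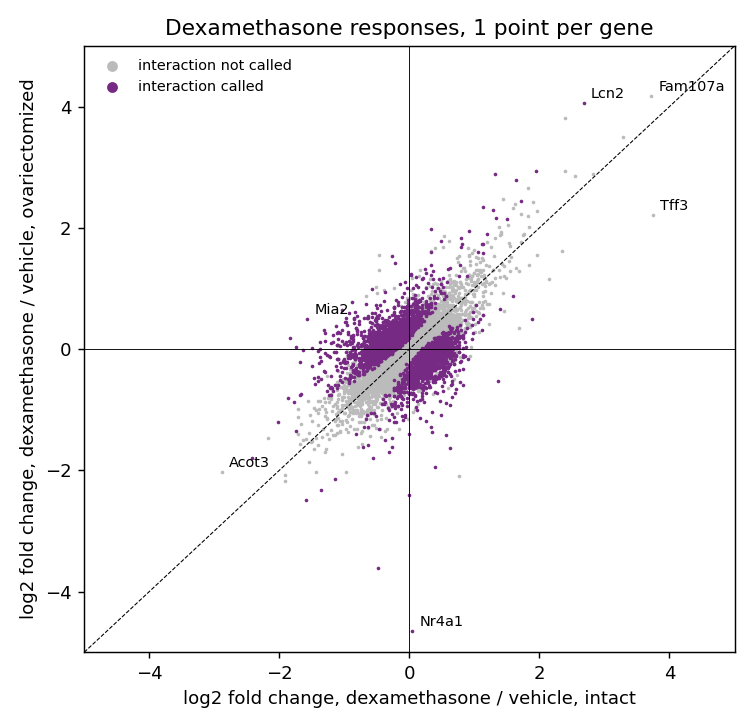
Each point is a gene, placed by its log2 fold change with dexamethasone in intact (x axis) and ovariectomized (y axis) females, n = 3 libraries per group, and purple points passed the test of the difference between the responses. Points spread around the dashed line of equal response (Pearson's r 0.58 across genes), Nr4a1 lies far below it, at -4.65 ± 0.28 in ovariectomized females, and Mia2 lies above it.

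Without dexamethasone, ovariectomized livers differed from intact livers in the immediate early gene Nr4a1, some major urinary protein genes and the oestrogen receptor gene. Nr4a1 was higher by 4.64 ± 0.28, adjusted p = 1.02e-05, at 11.14 ± 0.79 (mean ± SD) against 6.51 ± 0.13 in intact females. Ppp1r3g was higher by 3.21 ± 0.3, Nr4a2 by 2.33 ± 0.22 and Btbd19 by 2.23 ± 0.2. Esr1 (Entrez 13982) was lower (-1.39 ± 0.35, adjusted p = 0.0132), at 8.11 ± 0.094 against 9.5 ± 0.069. Mup2 (Entrez 17841) encodes a major urinary protein, secreted by liver and more abundant in males, and was higher by 2.76 ± 0.37. Mup13 (2.57 ± 0.39), Mup15 (2.52 ± 0.42), Mup19 (2.26 ± 0.46), Mup12 (2.11 ± 0.46) and Mup8 (2.1 ± 0.47) were higher too. These genes share 78.2% to 100% of their 50-base words with other genes, so the member that differed is uncertain. Of 17 Mup genes tested, a family counted after its values were seen, 7 were higher and 0 lower (the same recentred or under quantile normalization). Mup20 differed by 0.59 ± 0.16, adjusted p = 0.0594 to 0.0605 without replicate 1 of intact vehicle or 2 of ovariectomized vehicle and 0.0529 with the length and GC trend removed (0.00642 to 0.0605 over all alternatives). Mup1 (1.02 ± 0.49, adjusted p = 0.142) and Mup9 (0.07 ± 0.44, adjusted p = 0.914) did not pass.

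Igf2bp3, which encodes an RNA-binding protein, was lower in ovariectomized females (-1.76 ± 0.088), as were Abhd2 (-1.41 ± 0.16), Mia2, which encodes a protein of cargo export from the endoplasmic reticulum (-1.3 ± 0.13), Slfn9 (-1.23 ± 0.16), Rnf125 (-1.19 ± 0.2) and the uric acid pathway gene Urad (-1.19 ± 0.13). Rps7 was lower too (-1.28 ± 0.13) but is uncertain, since 27.7% of its words occur in another gene. Prtn3, a proteinase of neutrophil granules, differed by -1.19 ± 0.32, adjusted p = 0.0559 without ovariectomized vehicle replicate 2. Of other neutrophil markers, S100a9 differed by 0.65 ± 0.22, adjusted p = 0.0533 to 0.175 without replicate 1 or 3 of intact vehicle, 1 of intact dexamethasone, 2 or 3 of ovariectomized vehicle or 1, 2 or 3 of ovariectomized dexamethasone. Lcn2 differed by -0.63 ± 0.2, adjusted p = 0.0878 to 0.0958 without replicate 2 of intact vehicle or 1 or 2 of ovariectomized vehicle, and S100a8 (0.44 ± 0.24, adjusted p = 0.193) and Csf3r (0.24 ± 0.09, adjusted p = 0.0612) did not pass. Nr3c1 was lower (-0.43 ± 0.054). Per1 differed by 0.56 ± 0.16, adjusted p = 0.0548 to 0.0955 without replicate 2 or 3 of intact vehicle or 1 or 3 of ovariectomized vehicle. Fkbp5 (-0.59 ± 0.22, adjusted p = 0.0635) and Tsc22d3 (-0.25 ± 0.15, adjusted p = 0.233) did not pass. Apart from single libraries left out, the adjusted p was at most 0.0548 for Per1 with the length and GC trend removed (0.00231 to 0.0955 over all alternatives), 0.119 for S100a9 with the length and GC trend removed (0.0217 to 0.175 over all alternatives) and 0.0521 for Lcn2 with the replicate number as a block (0.0107 to 0.0958 over all alternatives).

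Of immediate early and heat shock genes, 11 of 20 were higher and 0 lower (11 and 0 adjusted over the list alone), with a median difference of 0.71. Immediate early genes had a camera adjusted p of 1.05e-05 (adjusted p = 0.724 with an estimated correlation), with the stress-induced factor Atf3 at 1.77 ± 0.31, Ier3 at 1.39 ± 0.17 and Fos at 1.31 ± 0.32. Of acute phase proteins, 2 of 27 were higher and 11 lower (2 and 15 adjusted over the list alone). Acute phase proteins had a camera adjusted p of 0.00179 (adjusted p = 0.984 with an estimated correlation), and adjusted p = 0.059 without intact vehicle replicate 2. The interleukin 6 receptor gene Il6ra was lower (-1.17 ± 0.15), and Socs3, a feedback inhibitor of cytokine signalling, was higher (0.7 ± 0.11). Of interferon response genes, 1 of 32 was higher and 17 lower (1 and 20 adjusted over the list alone). Interferon response genes had a camera adjusted p of 3.27e-06 (adjusted p = 0.724 with an estimated correlation), with Gbp7 at -0.83 ± 0.11, Ifit2 at -0.75 ± 0.11 and Gbp6 at -0.72 ± 0.11. Of cell cycle genes, 0 of 25 were higher and 7 lower (0 and 7 adjusted over the list alone). Cell cycle genes had a camera adjusted p of 0.00106 (adjusted p = 0.984 with an estimated correlation, 0.104 with fry), with the replication helicase gene Mcm6 at -0.73 ± 0.17. Of Kupffer cell and macrophage markers, 0 of 17 were higher and 8 lower (0 and 8 adjusted over the list alone). Macrophage markers had a camera adjusted p of 0.00106 (adjusted p = 0.984 with an estimated correlation, 0.0506 with fry), with Emr1, which encodes F4/80, at -0.88 ± 0.12 and Cd5l at -0.57 ± 0.091.

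Lists of sex-biased genes did not pass in vehicle-treated females. Of female-biased liver genes, 0 of 26 were higher and 3 lower (0 and 2 adjusted over the list alone), with a camera adjusted p of 0.224; Slc22a26 differed by -0.64 ± 0.13 and Abcd2 by -0.5 ± 0.067. Of male-biased liver genes, 2 of 15 were higher and 1 lower (2 and 1 adjusted over the list alone), with a camera adjusted p of 0.872, and Gstp1 differed by 0.53 ± 0.097. Of xenobiotic metabolism genes, 5 of 29 were higher and 6 lower (7 and 7 adjusted over the list alone), with a camera adjusted p of 0.904. The median (-0.03) and mean (0.04) of that list differed in sign. The glutathione transferase genes Gsta1 and Gstm1 were at 1.4 ± 0.26 and 0.84 ± 0.085 and Ugt1a1, the bilirubin glucuronosyltransferase gene, at -0.77 ± 0.087. The adjusted p was 0.0723 for Gstp1 with the length and GC trend removed (0.00022 to 0.0723 over all alternatives).

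In vehicle-treated females 1608 genes were higher and 2010 lower after ovariectomy (limma adjusted p under 0.05), with 43 and 23 at least 2-fold, and 5 lists passed (0 with an estimated correlation). The counts were 2675 and 3244 with library weights, 949 and 1266 without intact vehicle replicate 1, and 1055 genes were higher without intact vehicle replicate 3. The difference followed transcript length across genes (Spearman's rho -0.4; 0.33 for the difference between responses), the intact vehicle libraries holding relatively more of the long transcripts (rho 0.12 to 0.38) than all others (-0.23 to 0.02). With each library's trend on length and GC content removed, a step chosen after seeing the data, 1135 genes were higher and 1254 lower.

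**Figure D3:**
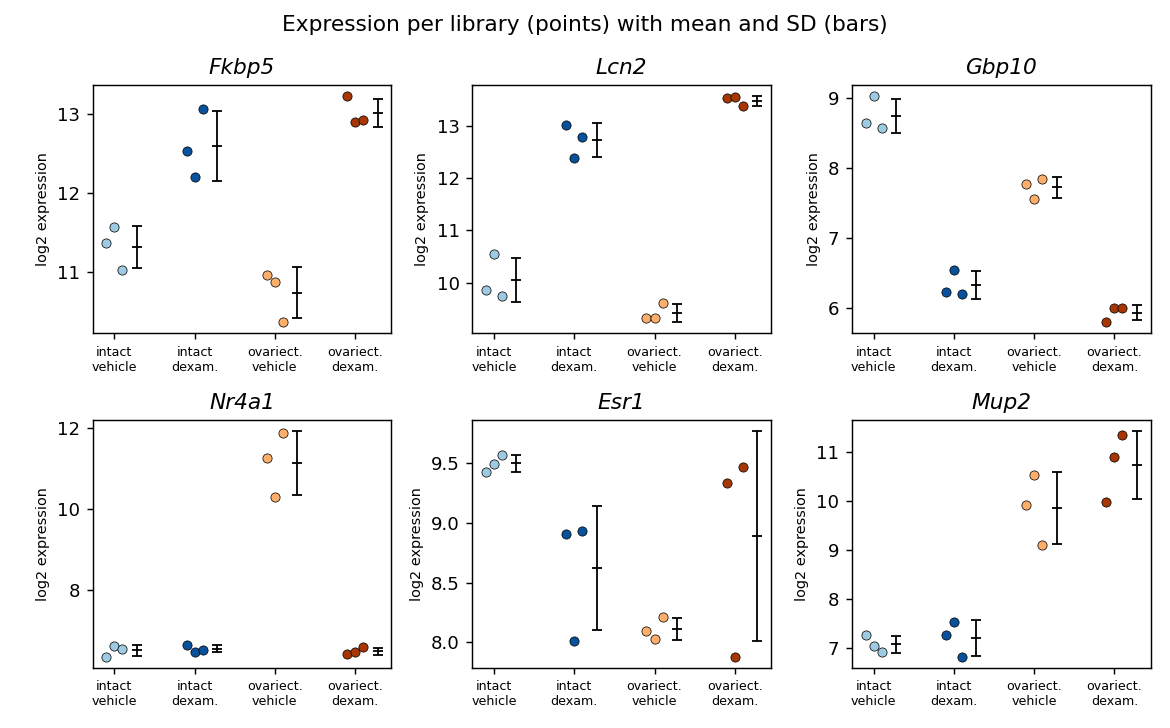
Points are log2 expression values (y axis) of 6 genes in the 12 libraries by group (x axis), and bars give each group's mean and SD (n = 3). Fkbp5 and Lcn2 are higher and Gbp10 lower with dexamethasone in both gonadal states, Nr4a1 is high in ovariectomized vehicle livers alone, 1 dexamethasone library of each gonadal state lies low for Esr1, and Mup2 is higher in ovariectomized females under both treatments.

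With dexamethasone, 8 of the 17 Mup genes tested were higher and 0 lower in ovariectomized than in intact livers (the same recentred or under quantile normalization). Mup2 was higher by 3.52 ± 0.37, adjusted p = 0.000821, at 10.73 ± 0.69 (mean ± SD) against 7.21 ± 0.36. Mup13 (3.42 ± 0.39), Mup19 (3.41 ± 0.46), Mup15 (3.1 ± 0.42) and Mup12 (2.86 ± 0.46) were higher too and, with 78.2% to 100% of their 50-base words shared, are uncertain as single genes. Cidec (Entrez 14311), a lipid droplet protein, was higher by 1.52 ± 0.23. Igf2bp3 was lower (-1.29 ± 0.088), and so was Rps10 (-1.49 ± 0.12), of whose words 22.6% are shared.

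The calls of 12 of the 20 largest differences ended without 1 library. Mup8 differed by 2.62 ± 0.47, adjusted p = 0.0501 without ovariectomized dexamethasone replicate 3. Mup1 differed by 2.43 ± 0.49, adjusted p = 0.053 to 0.0689 without replicate 1 of intact dexamethasone or 3 of ovariectomized dexamethasone, and Mup9 by 1.86 ± 0.44, adjusted p = 0.0538 to 0.0977 without replicate 1 or 3 of intact dexamethasone or 2 or 3 of ovariectomized dexamethasone. Lars2, the mitochondrial leucyl-tRNA synthetase gene, differed by 1.96 ± 0.57, adjusted p = 0.0506 to 0.143 without replicate 1, 2 or 3 of intact vehicle, 1, 2 or 3 of intact dexamethasone, 1, 2 or 3 of ovariectomized vehicle or 2 or 3 of ovariectomized dexamethasone. Lars2 was at 15.5 and 16.44 in ovariectomized dexamethasone replicates 2 and 3 and at 13.31 in replicate 1. The collagen gene Col3a1 differed by -1.28 ± 0.24, adjusted p = 0.053 without ovariectomized dexamethasone replicate 3. Col1a1 differed by -1.2 ± 0.25, adjusted p = 0.0629 to 0.0658 without replicate 1 of intact dexamethasone or 3 of ovariectomized dexamethasone. The proliferation marker Mki67 differed by -1.28 ± 0.31, adjusted p = 0.0538 to 0.0821 without replicate 1 or 3 of intact dexamethasone or 2 or 3 of ovariectomized dexamethasone. The mitotic gene Cdc20 differed by -1.23 ± 0.33, adjusted p = 0.0564 to 0.0962 without replicate 1 or 3 of intact dexamethasone or 1, 2 or 3 of ovariectomized dexamethasone. Ube2c, another mitotic gene, differed by -1.2 ± 0.33, adjusted p = 0.0507 to 0.108 without replicate 1 or 3 of intact vehicle, 1 or 3 of intact dexamethasone, 1 of ovariectomized vehicle or 1, 2 or 3 of ovariectomized dexamethasone. Ckap2l differed by -1.24 ± 0.36, adjusted p = 0.051 to 0.11 without replicate 1 of intact vehicle, 1 or 3 of intact dexamethasone, 1 or 3 of ovariectomized vehicle or 1, 2 or 3 of ovariectomized dexamethasone. Selenbp2, with 43.9% of its words shared, differed by -1.48 ± 0.38, adjusted p = 0.0703 to 0.0836 without replicate 1 or 3 of intact dexamethasone or 2 or 3 of ovariectomized dexamethasone. Rps28 differed by -1.39 ± 0.34, adjusted p = 0.0587 to 0.0729 without replicate 2 or 3 of intact dexamethasone or 1 or 2 of ovariectomized dexamethasone. Nr3c1 (0.11 ± 0.054, adjusted p = 0.208), Fkbp5 (0.42 ± 0.22, adjusted p = 0.209), Per1 (0.28 ± 0.16, adjusted p = 0.26) and Tsc22d3 (0.29 ± 0.15, adjusted p = 0.212) did not pass. Esr1 did not pass either (0.27 ± 0.35, adjusted p = 0.625), and its value was -0.03 without intact dexamethasone replicate 2 and -0.02 without ovariectomized dexamethasone replicate 3. Apart from single libraries left out, the adjusted p was at most 0.0609 for Mup9 with only the libraries compared (0.000495 to 0.0977 over all alternatives), 0.124 for Lars2 with only the libraries compared (0.00072 to 0.143 over all alternatives) and 0.0622 for Mki67 with only the libraries compared (0.000719 to 0.0821 over all alternatives). It was at most 0.0823 for Cdc20 with only the libraries compared (0.00205 to 0.0962 over all alternatives), 0.106 for Ube2c with only the libraries compared (0.00111 to 0.108 over all alternatives), 0.0779 for Ckap2l with quantile normalization (0.00385 to 0.11 over all alternatives) and 0.0711 for Rps28 with library weights (0.0186 to 0.0729 over all alternatives).

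Of fatty acid oxidation and PPARalpha targets, 14 of 30 were higher and 0 lower (22 and 0 adjusted over the list alone) in ovariectomized livers given dexamethasone. The oxidation list had a camera adjusted p of 5.84e-08 (adjusted p = 0.484 with an estimated correlation). Of xenobiotic metabolism genes, 5 of 29 were higher and 0 lower (9 and 0 adjusted over the list alone). Xenobiotic metabolism had a camera adjusted p of 4.6e-05 (adjusted p = 0.484 with an estimated correlation), with Ugt1a1 at 0.69 ± 0.087 and the bile pigment transporter gene Abcc2 at 0.43 ± 0.061. Of amino acid catabolism genes, 5 of 36 were higher and 1 lower (8 and 1 adjusted over the list alone). They had a camera adjusted p of 0.00463 (adjusted p = 0.524 with an estimated correlation, 0.0883 with fry), and adjusted p = 0.52 under quantile normalization (0.00104 to 0.524 over all alternatives), and their median of 0.16 became -0.03 under quantile normalization. Of cell cycle genes, 0 of 25 were higher and 10 lower (0 and 15 adjusted over the list alone). Cell cycle genes had a camera adjusted p of 5.84e-08 (adjusted p = 0.484 with an estimated correlation, 0.0533 with fry). Of interferon response genes, 0 of 32 were higher and 16 lower (0 and 18 adjusted over the list alone). Interferon response genes had a camera adjusted p of 2.41e-11 (adjusted p = 0.196 with an estimated correlation), with Ifit1 at -0.7 ± 0.093, Rsad2 at -0.67 ± 0.12 and Ifit3 at -0.66 ± 0.1.

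Of Kupffer cell and macrophage markers, 0 of 17 were higher and 7 lower (0 and 14 adjusted over the list alone) in ovariectomized livers given dexamethasone. Macrophage markers had a camera adjusted p of 2.65e-07 (adjusted p = 0.484 with an estimated correlation). Of sinusoidal endothelial markers, 0 of 16 were higher and 2 lower (0 and 4 adjusted over the list alone). Endothelial markers had a camera adjusted p of 0.00042 (adjusted p = 0.484 with an estimated correlation, 0.131 with fry). Of stellate cell and fibroblast markers, 0 of 16 were higher and 5 lower (0 and 5 adjusted over the list alone). Stellate markers had a camera adjusted p of 3.11e-05 (adjusted p = 0.484 with an estimated correlation, 0.0803 with fry). The lists of cholangiocytes (0 of 8 higher and 0 lower, camera adjusted p = 0.0686), B cells (0 of 7 higher and 0 lower, camera adjusted p = 0.0594) and T and NK cells (0 of 12 higher and 3 lower, camera adjusted p = 0.0609) did not pass.

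Of all genes tested, 1004 were higher and 658 lower (limma adjusted p under 0.05), and 14 lists passed (0 with an estimated correlation). The split of 60.4% higher became 48.2% (728 and 782 genes) with each library recentred to the same median. The counts were 400 and 368 under quantile normalization, 398 and 203 with only the libraries compared and 3289 and 2488 with library weights. The difference followed expression level across genes (Spearman's rho 0.42, and 0.33 for the difference between responses). No alternative fitted this trend, so its part in the list calls of both comparisons was not tested. The lower quartile of log2 values was 6.94 to 6.98 in ovariectomized dexamethasone libraries and 7.01 to 7.08 in the others. The counts rested on single libraries: 145 higher and 62 lower without ovariectomized dexamethasone replicate 3, 575 and 347 without its replicate 1, 322 lower without its replicate 2, and 204 and 108 without intact dexamethasone replicate 1.

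The genes that differed between ovariectomized and intact livers overlapped no more than independent lists in the same direction. Both treatments called 93 genes higher, Mup2, Mup13, Mup15, Mup19 and Mup12 among them, where independent lists of these sizes would share 124.5. Both called 102 lower, Igf2bp3 among them, where independent lists would share 102. A further 370 genes were lower under vehicle and higher under dexamethasone, against 155.7 for independent lists, and 68 were higher and then lower, against 81.6. Across genes Pearson's r of the differences was 0.04 (0.38 among genes with copies, -0.07 among those sharing no words) and Spearman's rho -0.1.

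In a test of whether the dexamethasone response itself differed between gonadal states, Nr4a1 differed most, by -4.69 ± 0.39, adjusted p = 0.000148: its response was 0.04 ± 0.28 in intact females and -4.65 ± 0.28 in ovariectomized females. Ppp1r3g (-3.12 ± 0.42), Nr4a2 (-2.39 ± 0.31), Ankrd37 (-2.33 ± 0.35) and Btbd19 (-2.26 ± 0.29) also had lower responses in ovariectomized females. Mia2 (2.06 ± 0.18, adjusted p = 0.000155), Abhd2 (2.02 ± 0.23), the interleukin 6 receptor gene Il6ra (1.8 ± 0.21), Rnf125 (1.78 ± 0.28) and Nrip1, a nuclear receptor corepressor (1.66 ± 0.15), had higher ones.

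Pdpr, which encodes a regulator of pyruvate dehydrogenase phosphatase (1.63 ± 0.22), and Gpam, the mitochondrial glycerol-3-phosphate acyltransferase gene (1.62 ± 0.27), had higher responses too. Lower responses were also those of Atf3 (-1.98 ± 0.44), Ier3 (-1.72 ± 0.24), Nupr1 (-1.61 ± 0.4) and Klf10 (-1.55 ± 0.36). Esr1 differed by 1.66 ± 0.49, adjusted p = 0.0502 to 0.0701 without replicate 1 or 3 of intact vehicle, 2 of intact dexamethasone, 1, 2 or 3 of ovariectomized vehicle or 1 or 3 of ovariectomized dexamethasone. Tsku differed by 1.65 ± 0.54, adjusted p = 0.0589 to 0.107 without replicate 1 or 3 of intact vehicle, 1 or 2 of intact dexamethasone, 1 or 3 of ovariectomized vehicle or 1 or 3 of ovariectomized dexamethasone. Onecut1, a hepatocyte transcription factor gene with 52.3% of its words shared, differed by 1.64 ± 0.47, adjusted p = 0.0556 to 0.0645 without replicate 3 of intact vehicle, 1 of intact dexamethasone, 1 or 3 of ovariectomized vehicle or 2 or 3 of ovariectomized dexamethasone. Fos differed by -1.58 ± 0.45, adjusted p = 0.0502 to 0.0565 without replicate 1 or 3 of intact vehicle, 1 of intact dexamethasone or 2 or 3 of ovariectomized dexamethasone. Fkbp5 differed by 1.01 ± 0.31, adjusted p = 0.0535 to 0.074 without replicate 1 or 2 of intact vehicle, 1 or 2 of intact dexamethasone, 3 of ovariectomized vehicle or 1 or 3 of ovariectomized dexamethasone. Nr3c1 differed by 0.54 ± 0.077, and Per1 (-0.28 ± 0.23, adjusted p = 0.387) and Tsc22d3 (0.54 ± 0.21, adjusted p = 0.0817) did not pass. Apart from single libraries left out, the adjusted p was at most 0.0628 for Esr1 with the length and GC trend removed (0.0019 to 0.0701 over all alternatives), 0.0725 for Tsku with a robust prior (0.00068 to 0.107 over all alternatives) and 0.105 for Fkbp5 with quantile normalization (0.00682 to 0.105 over all alternatives).

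Of immediate early and heat shock genes, 0 of 20 had a higher and 9 a lower response (0 and 9 adjusted over the list alone) in ovariectomized females. Immediate early genes had a camera adjusted p of 0.000237 (adjusted p = 0.846 with an estimated correlation). Of acute phase proteins, 11 of 27 had a higher and 1 a lower response (13 and 1 adjusted over the list alone). Acute phase proteins had a camera adjusted p of 0.000646 (adjusted p = 0.846 with an estimated correlation), with Lcn2 at 1.38 ± 0.28. Of fatty acid oxidation and PPARalpha targets, 12 of 30 had a higher and 0 a lower response (14 and 0 adjusted over the list alone). The oxidation list had a camera adjusted p of 0.00029 (adjusted p = 0.846 with an estimated correlation, 0.0821 with fry), with Cidec at 1.31 ± 0.32 and the peroxisome proliferation gene Pex11a at 1.22 ± 0.32. Of amino acid catabolism genes, 10 of 36 had a higher and 0 a lower response (10 and 0 adjusted over the list alone), with Cps1 at 1.04 ± 0.17 and Aass at 0.87 ± 0.16. Amino acid catabolism had a camera adjusted p of 0.0367 (adjusted p = 0.846 with an estimated correlation, 0.126 with fry), adjusted p = 0.0523 to 0.139 without replicate 2 of intact vehicle, 1 of intact dexamethasone, 1 or 2 of ovariectomized vehicle or 2 or 3 of ovariectomized dexamethasone, and adjusted p = 0.954 under quantile normalization (0.000453 to 0.954 over all alternatives). Its median of 0.18 became -0.01 under quantile normalization. Of bile acid synthesis and transport genes, 5 of 19 had a higher and 0 a lower response (5 and 0 adjusted over the list alone). This group had a camera adjusted p of 0.0367 (adjusted p = 0.846 with an estimated correlation), adjusted p = 0.0523 to 0.086 without replicate 1 of intact vehicle, 3 of intact dexamethasone, 1 or 2 of ovariectomized vehicle or 2 or 3 of ovariectomized dexamethasone, and adjusted p = 0.573 under quantile normalization (0.00867 to 0.846 over all alternatives). Akr1d1 differed by 0.66 ± 0.15, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 0.97 ± 0.26, adjusted p = 0.0517 without intact dexamethasone replicate 1. Of xenobiotic metabolism genes, 6 of 29 had a higher and 1 a lower response (6 and 1 adjusted over the list alone), with Ugt1a1 at 1.46 ± 0.12 and the cytochrome P450 reductase gene Por at 0.82 ± 0.14. Xenobiotic metabolism had a camera adjusted p of 0.0367 (adjusted p = 0.846 with an estimated correlation), adjusted p = 0.0559 to 0.127 without replicate 2 of intact vehicle, 1 of intact dexamethasone, 1 or 2 of ovariectomized vehicle or 3 of ovariectomized dexamethasone, and adjusted p = 0.506 under quantile normalization (0.00729 to 0.846 over all alternatives). Apart from single libraries left out, the adjusted p was at most 0.093 for Cyp7a1 with quantile normalization (0.000747 to 0.093 over all alternatives).

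Of stellate cell and fibroblast markers, 0 of 16 had a higher and 4 a lower response (0 and 8 adjusted over the list alone) in ovariectomized females. Stellate markers had a camera adjusted p of 0.00151 (adjusted p = 0.846 with an estimated correlation, 0.137 with fry). The smooth muscle actin gene Acta2 differed by -1.36 ± 0.44, adjusted p = 0.0501 to 0.0961 without replicate 1, 2 or 3 of intact vehicle, 1 or 3 of ovariectomized vehicle or 1, 2 or 3 of ovariectomized dexamethasone. Tagln differed by -0.81 ± 0.27, adjusted p = 0.0519 to 0.106 without replicate 1, 2 or 3 of intact vehicle, 1 or 3 of intact dexamethasone, 1 or 3 of ovariectomized vehicle or 1, 2 or 3 of ovariectomized dexamethasone. Of sinusoidal endothelial markers, 0 of 16 had a higher and 3 a lower response (0 and 3 adjusted over the list alone), with Clec4g at -0.43 ± 0.11. Endothelial markers had a camera adjusted p of 0.0367 (adjusted p = 0.846 with an estimated correlation, 0.3 with fry), and adjusted p = 0.107 to 0.202 without replicate 2 of intact vehicle, 3 of intact dexamethasone, 1 of ovariectomized vehicle or 3 of ovariectomized dexamethasone. Stab2 differed by -0.39 ± 0.11, adjusted p = 0.0533 to 0.0673 without replicate 3 of intact vehicle, 1 of intact dexamethasone, 1 of ovariectomized vehicle or 1 or 3 of ovariectomized dexamethasone. Of cholangiocyte markers, 0 of 8 had a higher and 2 a lower response (0 and 2 adjusted over the list alone), with Spp1 at -0.7 ± 0.12 and Epcam at -0.51 ± 0.11. Cholangiocyte markers had a camera adjusted p of 0.0339 (adjusted p = 0.846 with an estimated correlation), adjusted p = 0.0504 to 0.0614 without replicate 2 of intact vehicle or 3 of ovariectomized dexamethasone, and adjusted p = 0.306 under quantile normalization (0.00646 to 0.846 over all alternatives). The lists of macrophages (2 of 17 higher and 2 lower, camera adjusted p = 0.855), B cells (0 of 7 higher and 0 lower, camera adjusted p = 0.338) and T and NK cells (0 of 12 higher and 2 lower, camera adjusted p = 0.177) did not pass. Of neutrophil markers, not tested as a list, Csf3r differed by -0.71 ± 0.13 and Lcn2, also an acute phase gene, by 1.38 ± 0.28. S100a9 differed by -1.07 ± 0.31, adjusted p = 0.0506 to 0.0712 without replicate 1 or 3 of intact vehicle, 1 or 3 of intact dexamethasone, 3 of ovariectomized vehicle or 1 or 2 of ovariectomized dexamethasone, and S100a8 (-0.6 ± 0.34, adjusted p = 0.216) did not pass. Apart from single libraries left out, the adjusted p was at most 0.0628 for Acta2 with quantile normalization (0.0103 to 0.0961 over all alternatives), 0.0917 for Tagln with the length and GC trend removed (0.00613 to 0.106 over all alternatives), 0.0617 for Clec4g with the length and GC trend removed (3e-04 to 0.0617 over all alternatives) and 0.0649 for S100a9 with quantile normalization (0.00618 to 0.0712 over all alternatives).

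In total the response was higher in ovariectomized females for 1983 genes and lower for 1251 (limma adjusted p under 0.05), or for 3651 and 3008 with library weights, 1744 and 1519 recentred to the same median, 1419 and 1308 under quantile normalization. Of the 1983, 984 were called between ovariectomized and intact livers under vehicle alone, 319 under dexamethasone alone, 372 under both and 308 under neither. Of the 1251, these were 755, 206, 76 and 214, a description that uses the same libraries as the test. The lower count was 822 without intact vehicle replicate 1 and 741 without intact dexamethasone replicate 1. The 9 lists that passed became 5 without ovariectomized vehicle replicate 1, 4 without ovariectomized dexamethasone replicate 3 and 0 with an estimated correlation.

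**Figure D4:**
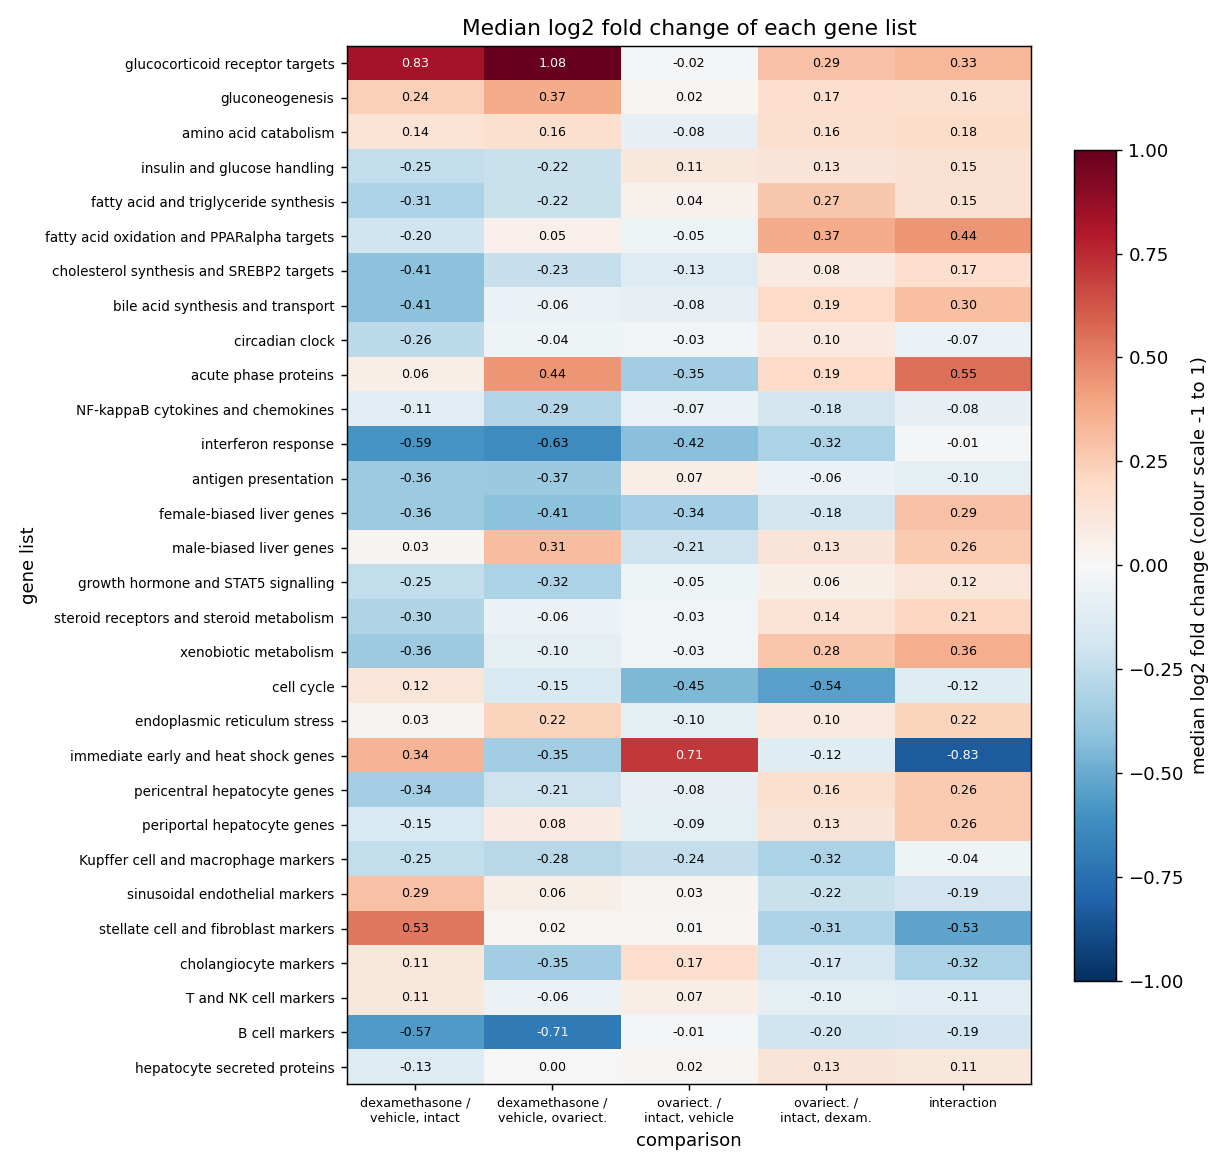
Cells give the median log2 fold change of the measured members of each of 30 gene lists (y axis) in the 5 comparisons (x axis), n = 3 libraries per group, on a colour scale from -1 to 1. Glucocorticoid receptor targets have medians of 0.83 and 1.08 under dexamethasone, interferon response genes lie below 0 in the 4 comparisons of groups, and immediate early and heat shock genes are at 0.71 in ovariectomized vehicle livers.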

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

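The patterns weighed here were seen in a first fit before the tests of technical explanations were set. The tests of gene copies among genes called under both treatments, and the length and GC trend removal, were chosen after seeing the result. Genes and lists in the first 3 paragraphs had responses to dexamethasone that differed between gonadal states, genes by limma and lists by camera, with n = 3 libraries per group; with an estimated correlation 0 lists did (lowest adjusted p = 0.846). The response was higher in ovariectomized females for 1983 genes and lower for 1251 (1744 and 1519 recentred to the same median, 1419 and 1308 under quantile normalization). Of 100 splits drawn from 200, 1, the real one, reached the count of 3234 genes (highest other 2037). Mixed splits hold group differences in their residual, which can lower their counts, so this test cannot exclude chance. Nor can it for the 9 lists called, reached by 72 splits (highest other 19).

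Lists with higher responses in ovariectomized females by camera had median differences of 0.18 (amino acid catabolism; adjusted p = 0.126 with fry and 0.954 under quantile normalization, which turned the median to -0.01), 0.44 (fatty acid oxidation; adjusted p = 0.0821 with fry), 0.3 (bile acid synthesis; adjusted p = 0.573 under quantile normalization), 0.55 (acute phase proteins) and 0.36 (xenobiotic metabolism; adjusted p = 0.506 under quantile normalization). Each had adjusted p = 0.846 with an estimated correlation. Lists with lower responses had medians of -0.83 (immediate early and heat shock genes), -0.19 (sinusoidal endothelium; adjusted p = 0.3 with fry), -0.53 (stellate cells; adjusted p = 0.137 with fry) and -0.32 (cholangiocytes; adjusted p = 0.306 under quantile normalization). Each had adjusted p = 0.846 with an estimated correlation. Higher responses were those of Mia2 (2.06 ± 0.18), Abhd2 (2.02 ± 0.23), Il6ra (1.8 ± 0.21), Rnf125 (1.78 ± 0.28), Nrip1 (1.66 ± 0.15), Pdpr (1.63 ± 0.22), Gpam (1.62 ± 0.27), Ugt1a1 (1.46 ± 0.12), Lcn2 (1.38 ± 0.28), Cidec (1.31 ± 0.32), Pex11a (1.22 ± 0.32), Cps1 (1.04 ± 0.17), Aass (0.87 ± 0.16), Por (0.82 ± 0.14), Akr1d1 (0.66 ± 0.15) and Nr3c1 (0.54 ± 0.077). Lower responses were those of Nr4a1 (-4.69 ± 0.39), Ppp1r3g (-3.12 ± 0.42), Nr4a2 (-2.39 ± 0.31), Ankrd37 (-2.33 ± 0.35), Btbd19 (-2.26 ± 0.29), Atf3 (-1.98 ± 0.44), Ier3 (-1.72 ± 0.24), Nupr1 (-1.61 ± 0.4), Klf10 (-1.55 ± 0.36), Spp1 (-0.7 ± 0.12), Epcam (-0.51 ± 0.11) and Clec4g (-0.43 ± 0.11, adjusted p = 0.0617 with the trend removed).

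The calls of some of these genes ended without 1 library (adjusted p given here). Esr1 differed by 1.66 (adjusted p = 0.0502 to 0.0701 without 1 of 8 libraries). Tsku differed by 1.65 (adjusted p = 0.0589 to 0.107 without 1 of 8 libraries). Onecut1 differed by 1.64 (adjusted p = 0.0556 to 0.0645 without 1 of 6 libraries). Fos differed by -1.58 (adjusted p = 0.0502 to 0.0565 without 1 of 5 libraries). Fkbp5 differed by 1.01 (adjusted p = 0.0535 to 0.074 without 1 of 7 libraries). Cyp7a1 differed by 0.97 (adjusted p = 0.0517 without intact dexamethasone replicate 1). Acta2 differed by -1.36 (adjusted p = 0.0501 to 0.0961 without 1 of 8 libraries). Tagln differed by -0.81 (adjusted p = 0.0519 to 0.106 without 1 of 10 libraries). Stab2 differed by -0.39 (adjusted p = 0.0533 to 0.0673 without 1 of 5 libraries).

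Of immediate early and heat shock genes 11 of 20 were higher in ovariectomized than in intact vehicle livers, and 9 had a lower response to dexamethasone in ovariectomized females. The tables argue against 1 library as the source: without any 1 library at least 77.8% of the 9 immediate early genes called were still called. They also argue against heat shock in handling as the whole source, since heat shock genes had a median difference of 0.15 (-0.01 to 0.37), although Hspb1 stood at 1.14. A different time of day cannot be told apart, because genes that peak with Dbp and those that peak with Arntl differed by 0.05, with a range of -0.62 to 0.6 too wide to decide. Gonadal state, and handling other than heat, may be the source and were not tested.

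Long transcripts were low in ovariectomized relative to intact vehicle livers (Spearman's rho -0.4 across genes). Removing each library's trend on length and GC content lowered the number of genes whose responses differed from 3234 to 2534, a fall of 21.6%, between the bounds set before this result was seen. Of the genes called before, 62.2% were still called, and 51.3% of those called in vehicle livers. A difference in RNA quality or library preparation might lie behind the trend, but it cannot be told apart from gonadal state, since the labels give no batch and the trend lies in 1 group.

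Genes higher in ovariectomized females under both treatments held many with copies, such as the Mup genes. Genes with copies made up 22.8% of them against 10.2% of all genes (ratio 2.23, Fisher's exact p = 0.000368), and 14.7% of those lower under both (ratio 1.44, Fisher's exact p = 0.139). The tables argue against shared reads as a cause across all genes, because the test with a bound set before its result was seen gave a ratio of median absolute differences, copies over none, of 1.07 (1 to 1.17) under vehicle and 1.01 (0.94 to 1.08) under dexamethasone, below that bound. They also argue against a fall of nearly all ribosomal protein genes under both treatments, since 39.2% of 79 were lower under vehicle (12 called lower and 14 higher; with the trend removed 63.3%, 24 and 8) and 84.8% under dexamethasone (38 and 2). Their differences correlated between treatments (r 0.83, against 0.04 over all genes), so a cause common to part of them stays open, as do reads shared within the Mup family and an effect of gonadal state on these genes, untested here.

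For the other comparisons, the 6 libraries make 10 splits, too few for a share under 0.05. In intact females the real count of 6323 genes was reached in 1 split (highest other 0), in ovariectomized females 5283 in 1 (0), under vehicle 3618 in 1 (0) and under dexamethasone 1662 in 1 (8). List counts of 11, 11, 5 and 14 were reached in 5, 5, 10 and 3 splits, with highest others of 14, 13, 14 and 15.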

How the results depend on the processing

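Length and GC trend removal, leaving out genes with copies and recentring for list tests were chosen after seeing the data. With a minimum absolute log2 fold change of 1, fewer genes can pass: 135 higher and 178 lower for dexamethasone in intact females, 200 and 159 in ovariectomized females, 43 and 23 for ovariectomized against intact under vehicle, 16 and 24 under dexamethasone, and 112 and 53 for the difference between responses. Library weights gave 2675 and 3244 under vehicle, 3289 and 2488 under dexamethasone, and 3651 and 3008 for the difference between responses; the cause was not tested. With the trend removed 1254 genes were lower under vehicle, the cause not tested. Under dexamethasone, ovariectomized against intact gave 400 and 368 genes and 8 lists with quantile normalization (cause not tested). It gave 398 and 203 genes with only its own libraries (fewer samples) and 8 lists with fry. Fry asks another question and ended 17 of 50 list calls. With an estimated correlation 0 lists were called in any comparison.

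Leaving out 1 library at a time leaves fewer samples. For ovariectomized against intact under vehicle it gave 949 to 1788 genes higher and 1266 to 2201 lower, the lowest of both without intact vehicle replicate 1, and 1055 higher without intact vehicle replicate 3. Under dexamethasone it gave 145 to 1130 higher and 62 to 722 lower, lowest without ovariectomized dexamethasone replicate 3, with 204 and 108 without intact dexamethasone replicate 1, 575 and 347 without ovariectomized dexamethasone replicate 1, and 322 lower without its replicate 2. Lower responses numbered 741 to 1404, lowest without intact dexamethasone replicate 1, and 822 without intact vehicle replicate 1. Lists for dexamethasone in intact females numbered 6 to 12, lowest without intact dexamethasone replicate 3, and lists for the difference between responses 4 to 11, lowest without ovariectomized dexamethasone replicate 3 and 5 without ovariectomized vehicle replicate 1. Nr3c1 with dexamethasone in ovariectomized females ranged from -0.08 to 0.01, above 0 without ovariectomized dexamethasone replicate 2. Esr1 in ovariectomized against intact under dexamethasone ranged from -0.03 to 0.78, below 0 without intact dexamethasone replicate 2 or ovariectomized dexamethasone replicate 3 (-0.02). With quantile normalization Fgb with dexamethasone in ovariectomized females was at -0.04, and the median of amino acid catabolism at -0.03 in ovariectomized against intact under dexamethasone and -0.01 for the difference between responses; the cause was not tested.

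Over 555 results for named genes, 11389 values under all alternatives kept their direction and side of the threshold, 1202 lost the call, 19 gained it and 4 changed sign. For 50 called lists these were 766, 132, 0 and 2. Without any 1 library, the call was kept by 118 of 128 named genes called for dexamethasone in intact and 109 of 127 in ovariectomized females, 63 of 108 for ovariectomized against intact under vehicle, 18 of 77 under dexamethasone and 60 of 102 for the difference between responses. The correlation of the responses ranged from 0.55 to 0.61 and the score difference from -0.15 to -0.03 without 1 library. The replicate numbers were not taken to pair libraries, since 4 of 12 pairs correlated above 0.1 and 5 of 12 libraries lay closest to their own number. With the replicate number as a block the counts in the 5 comparisons were 2925 and 3316, 2661 and 2494, 1532 and 1918, 880 and 653 and 1906 and 1212, none moved by over 1.5 times, and the lists numbered 12, 11, 5, 14, 8. Depth is unknown, so what it limits cannot be stated.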

Other observations

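No test in this part was chosen after the result was seen. In intact females given dexamethasone, fatty acid and triglyceride synthesis genes went both ways. Of them, 3 of 24 rose and 9 fell (4 and 11 adjusted over the list alone), with a camera adjusted p of 0.099. Gpam changed by -1.63 ± 0.19 and Srebf1, which encodes the lipogenic transcription factor SREBP1, by -1.3 ± 0.2. In ovariectomized females 6 of 24 rose and 6 fell (6 and 7 adjusted over the list alone), with a camera adjusted p of 0.403. Thrsp, a lipogenesis-related gene, rose by 1.53 ± 0.37 and Acly, the ATP citrate lyase gene, changed by -1.31 ± 0.2. Among xenobiotic metabolism genes of intact females 5 of 29 rose and 14 fell (5 and 15 adjusted over the list alone), with a camera adjusted p of 0.099. Cyp2b10, a target of the receptor CAR, rose by 1.97 ± 0.13 in intact and 2.28 ± 0.13 in ovariectomized females, and Cyp2a5 changed by -1.2 ± 0.17 and -0.79 ± 0.17. Of growth hormone and STAT5 signalling genes in intact females, 1 of 14 rose and 4 fell (1 and 4 adjusted over the list alone), with a camera adjusted p of 0.215. The growth hormone receptor gene Ghr changed by -0.77 ± 0.082 and Igfbp3 by 0.73 ± 0.16. Of steroid receptors and steroid metabolism genes in intact females, 4 of 17 rose and 9 fell (5 and 10 adjusted over the list alone), with a camera adjusted p of 0.157. The mineralocorticoid receptor gene Nr3c2 changed by -1.72 ± 0.16 and the oestrogen-regulated gene Greb1 by 1.72 ± 0.22.

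In ovariectomized against intact livers given dexamethasone, 6 further lists passed, each losing its call without at least 1 library. Of all 12965 genes tested, 1004 were higher and 658 lower in this comparison. The counts of 2 of 24 and 2 of 27 genes higher, given below, lie near that share. Of glucocorticoid receptor targets, 3 of 23 were higher and 0 lower (5 and 0 adjusted over the list alone). Receptor targets had a camera adjusted p of 0.0135 (adjusted p = 0.524 with an estimated correlation, 0.155 with fry), and adjusted p = 0.0874 to 0.196 without replicate 2 of intact dexamethasone or 1 of ovariectomized dexamethasone. Of gluconeogenesis genes, 3 of 20 were higher and 1 lower (3 and 1 adjusted over the list alone). Gluconeogenesis had a camera adjusted p of 0.0269 (adjusted p = 0.484 with an estimated correlation), adjusted p = 0.0513 to 0.12 without replicate 1 or 2 of intact dexamethasone or 1 of ovariectomized dexamethasone, and adjusted p = 0.871 under quantile normalization (0.00234 to 0.871 over all alternatives), with the nuclear receptor gene Hnf4a at 0.59 ± 0.088 and the pyruvate carboxylase gene Pcx at 0.38 ± 0.063 (adjusted p = 0.125 under quantile normalization). Of fatty acid and triglyceride synthesis genes, 2 of 24 were higher and 0 lower (5 and 0 adjusted over the list alone). Lipid synthesis had a camera adjusted p of 0.0104 (adjusted p = 0.524 with an estimated correlation, 0.131 with fry), adjusted p = 0.0752 without ovariectomized dexamethasone replicate 3, and adjusted p = 0.341 under quantile normalization (0.0022 to 0.524 over all alternatives). Of bile acid synthesis and transport genes, 2 of 19 were higher and 0 lower (2 and 0 adjusted over the list alone). Bile acid genes had a camera adjusted p of 0.0228 (adjusted p = 0.484 with an estimated correlation), adjusted p = 0.0507 to 0.104 without replicate 3 of intact dexamethasone or 2 of ovariectomized dexamethasone, and adjusted p = 0.761 under quantile normalization (0.00238 to 0.761 over all alternatives), with Amacr at 0.41 ± 0.052. Of acute phase proteins, 2 of 27 were higher and 0 lower (2 and 0 adjusted over the list alone). Acute phase proteins had a camera adjusted p of 0.0334 (adjusted p = 0.53 with an estimated correlation, 0.132 with fry), adjusted p = 0.145 to 0.15 without replicate 2 of intact dexamethasone or 1 of ovariectomized dexamethasone, and adjusted p = 0.838 under quantile normalization (0.0133 to 0.838 over all alternatives). Of NF-kappaB cytokines and chemokines, 0 of 23 were higher and 3 lower (0 and 3 adjusted over the list alone). The cytokine list had a camera adjusted p of 0.0155 (adjusted p = 0.484 with an estimated correlation, 0.0883 with fry), adjusted p = 0.0675 without ovariectomized dexamethasone replicate 3, and adjusted p = 0.309 under quantile normalization (0.0045 to 0.484 over all alternatives).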
